A study of Arabidopsis with 18 samples.

How the data were processed

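The series holds 18 RNA-seq libraries of Arabidopsis seedling root tips, 3 in each of 6 groups: Col, arf2 and stop1, each without NAA (labelled CK) and with NAA. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy kit, cDNA was made with random primers, and libraries were sequenced on an Illumina instrument. The aligner, the counting program and the genome build were not given in the sources used here, and neither was whether the counting used strand.

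The authors deposited 6 tables, 1 per group, each with an estimated count and an expression value per gene and library. The estimated counts in the deposited tables were not normalized, and 21.3% of the nonzero values were not exactly whole as printed, with no tolerance, so they were rounded before testing. The expression values in the deposited tables behaved as FPKM: a count divided by its FPKM and the library total gave 1 length per gene, with a median coefficient of variation of 0.0015 over 18960 genes, and the values were not used for tests. Tables listed 23175 to 23414 genes each and 24838 together, and a gene missing from a table was taken as 0 there. All 24838 identifiers matched the RefSeq gene table of TAIR10.1, and 24316 had the same start and end, so coordinates are those of the deposited tables. Genes with near-identical copies, such as SAUR, LHCB and RBCS genes, and genes that overlap another, are uncertain to the extent that counting could divide their reads.

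Library totals were 22486010 to 23136350 estimated reads, and the 10 most abundant genes took 4.16 to 6.98% of a library. Replicates were compared by chi-square tests of their counts, and no pair agreed within sampling noise. Counting intervals cover counting error only, at a confidence level of 95%.

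Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter and a quasi-likelihood fit of 6 group means to all 18 libraries, with no covariates. Benjamini-Hochberg adjustment was over the 20602 genes tested, with a threshold of 0.05. A standard error is the absolute log2 change divided by the square root of the F statistic. The comparisons were NAA against no treatment in each genotype, each mutant label against Col with and without NAA, and the 2 differences of the NAA effect. CPM values are TMM-scaled, with n = 3 libraries per group.

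Before the data were examined, 25 gene lists were fixed, covering auxin and other hormone responses, nutrient and stress responses, the cell cycle, cell types of the root, photosynthetic tissue and genes published as activated by STOP1. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. Of 225 list tests 49 passed, and 9 of these held with an estimated correlation, namely Aux/IAA and lateral root initiation genes for NAA in each genotype, auxin conjugation and oxidation genes for NAA in stop1, and STOP1-activated genes in stop1 with and without NAA. Lists not named for a comparison did not pass camera there. Counts adjusted over the list alone used the same gene p-values. The value of 1 list member is not reported here.

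Genes were named by a rule fixed at the same time: up to 10 with the largest change in each direction for NAA effects and genotype comparisons without NAA, and up to 5 for the others. They needed an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, no overlap of values between groups (not for differences) and a symbol. The targeted genes and the members of each list with the largest changes, or against their list, were added. HSFB2A and HB33 values outside the comparisons where the rule named them, and the seed genes as a sum, were chosen after values were seen.

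Alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, library totals alone, no filter, a minimum mean of 5 CPM, only the groups compared, the replicate number as a block, an added 2-fold threshold, and leaving out each library in turn. After the data were seen, 4 were added: removal of the trend over transcript length, limma-voom with library weights, a fit without the libraries labelled arf2, and leaving out the pair of libraries with the steepest length trends. Each comparison was tested on simulated counts with 200 changed genes, drawn with the same spread per gene in every group. At 2-fold, 38 to 56% of changed genes were recovered in the 7 direct comparisons and 14% in both differences, and at 4-fold 84 to 93% and 73 to 76%.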

Results

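Transcripts of Arabidopsis seedling root tips were measured in 3 genotypes, each kept without NAA or given NAA, a synthetic auxin. The genotypes were the wild type Col, a line labelled arf2 and a line labelled stop1. ARF2 encodes an auxin response factor, and STOP1 encodes a zinc finger transcription factor known for its role in acid soil and aluminium tolerance. Each of the 6 groups held 3 libraries, 18 in all, with 22486010 to 23136350 estimated reads per library. Between 22123 and 22494 genes had at least 1 read in a library. The dose and the length of the treatment were not given in the sources used here. The labels did not say that replicates came from separate cultures, so p-values measure the spread between these samples only, which may be technical.

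The targeted genes were examined first, as a check of the labels. STOP1 (AT1G34370, chromosome 1, 12550339 to 12552629) had 191 ± 17.42 CPM (SD, n = 3) in untreated Col and 52.3 ± 6.47 CPM in untreated stop1. With NAA it had 239 ± 32.5 CPM in Col and 73.0 ± 9.92 CPM in stop1. The log2 change in stop1 was −1.87 ± 0.16 (SE) without NAA and −1.71 ± 0.16 with NAA, with adjusted p = 2.42e-06 and 4.53e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ARF2 (AT5G62000, chromosome 5, 24910191 to 24915395) had 125 ± 11.4 CPM in untreated Col and 83.7 ± 42.8 CPM in untreated arf2, where the libraries ranged from 34.3 to 109 CPM. The difference did not pass the same edgeR test with Benjamini-Hochberg adjustment, at log2 −0.58 ± 0.30 with adjusted p = 0.415 without NAA and −0.33 ± 0.30 with adjusted p = 0.412 with NAA. Voom weights alone called it with NAA, at −0.271 with adjusted p = 0.0258. ARF2 transcript level was lower on average but did not pass the edgeR test, so it did not check the label, and the samples are called the libraries labelled arf2. ARF2 was lowest at 34.3 CPM in arf2_CK replicate 2 and at 80.9 CPM in arf2_NAA replicate 3. In these libraries read levels fell most with transcript length, by log2 slopes of −0.366 and −0.605 per doubling. The other libraries labelled arf2 had 108 and 109 CPM without NAA and 134 and 116 CPM with NAA. In stop1, ARF2 had 133 ± 11.1 CPM without and 192 ± 27.6 CPM with NAA, against 139 ± 14.3 CPM in Col with NAA. In edgeR neither its NAA effect in stop1 nor stop1 against Col with NAA passed (adjusted p = 0.232 and 0.443). Without the arf2 libraries in the fit these were 0.546 and 0.505 (adjusted p = 0.00338 and 0.0112). Only the compared groups and voom weights also called both, and removal of the length trend the NAA effect. HSFB2A (AT5G62020, chromosome 5, 24915807 to 24917643), a heat shock factor gene, begins just beyond ARF2. Its reads numbered 1 to 23 in the 6 libraries labelled arf2 and 200 to 527 in the 12 others.

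**Figure D1:**
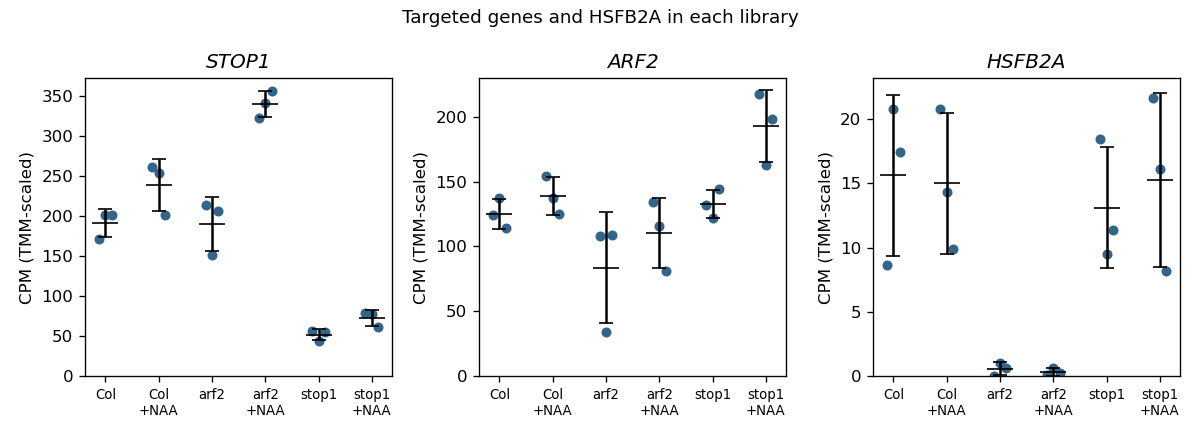
TMM-scaled CPM of STOP1, ARF2 and HSFB2A in each of the 18 libraries, by genotype and treatment. Points are libraries, and horizontal bars with whiskers are the mean ± SD of 3. STOP1 lay at 44.8 to 79.7 CPM in stop1 libraries and at 152 CPM or more in all others, while ARF2 lay at 34.3 to 109 CPM in the libraries labelled arf2 and 114 to 137 CPM in Col without NAA. With NAA the ARF2 ranges of 80.9 to 134 CPM and 125 to 154 CPM overlapped.

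The first question was what NAA changed in wild-type root tips. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, rose from 8.77 ± 1.61 to 2882 ± 64.6 CPM (SD, n = 3), a log2 change of 8.36 ± 0.24 (SE), and GH3.2 rose by 6.05 ± 0.32. The Aux/IAA repressor genes IAA5, IAA29 and IAA6 rose by 6.64 ± 0.32, 6.41 ± 0.35 and 6.38 ± 0.75. LBD29, a lateral root regulator, rose by 6.35 ± 0.21. ZFP2, GAD5 and OFP4 rose by 7.44 ± 0.56, 6.90 ± 0.55 and 6.70 ± 0.44. CYP78A10 had 2 reads in the untreated libraries and 545 with NAA, a ratio of 253 with a 95% counting interval of 69.7 to 2090. SKOR, a potassium channel gene of the root stele, fell from 23.9 ± 3.16 to 0.73 ± 0.12 CPM, a log2 change of −5.03 ± 0.25. Also lower were CYP78A6 at −4.85 ± 0.31, MYB48 at −4.63 ± 0.34, the peptide gene CLE2 at −4.63 ± 0.29, the aquaporin gene NLM1 at −4.48 ± 0.37. So were the expansin gene EXPB1 at −4.32 ± 0.27 and the sugar transporter gene SWEET12 at −4.22 ± 0.41. These genes had all 3 values of one group above all 3 of the other, and their adjusted p ranged from 7.43e-12 for GH3.3 to 8.93e-06 for IAA6 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

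Of 28 Aux/IAA genes tested in Col, 22 rose and 1, IAA27, fell, the same counts when adjusted over the list alone. Of 21 lateral root initiation genes, 17 rose, among them LBD33 by 5.71 ± 0.22, MAKR4 by 5.16 ± 0.26 and LBD17 by 5.09 ± 0.18. In this list 1 gene, EXPA14, fell, with the same counts adjusted over the list alone. Both lists passed camera with Benjamini-Hochberg adjustment (adjusted p = 3.01e-14 and 1.42e-16) and held with an estimated correlation (adjusted p = 0.000256 and 0.00022). Of 8 auxin conjugation and oxidation genes 6 rose, both over all genes and adjusted over the list alone, at adjusted p = 1.09e-07 in camera and adjusted p = 0.0727 with an estimated correlation. DNA replication genes rose in 11 of 14 cases, also 11 adjusted over the list alone, with MCM6 at 2.05 ± 0.41 and CYCD3;1 at 1.17 ± 0.14 (camera adjusted p = 0.000309, adjusted p = 0.117 with an estimated correlation). Of 19 auxin carrier and carrier kinase genes 10 rose, including PIN7 by 2.65 ± 0.18 and PID by 2.52 ± 0.21. In that list PIN5, WAG1 and PILS5 fell, so 3 were lower, the same counts adjusted over the list alone (camera adjusted p = 0.0146, adjusted p = 0.506 with an estimated correlation). Of 10 ethylene synthesis and response genes 5 rose, with ACS9, ACS8 and ACS11 at 5.07 ± 0.78, 4.69 ± 0.25 and 4.12 ± 0.33. Another 2 fell, ACS5 at −4.45 ± 0.70 and ACS7 at −1.59 ± 0.43, with the same counts adjusted over the list alone. That list had a camera adjusted p = 0.0303 and adjusted p = 0.117 with an estimated correlation, and its camera adjusted p was 0.0597 when libraries were scaled to their totals alone.

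Photosynthesis genes, markers of shoot or greening tissue, fell in 13 of 15 cases in Col and in 14 adjusted over the list alone, with LHCB1.1 at −2.38 ± 0.60 (camera adjusted p = 0.000181, adjusted p = 0.506 with an estimated correlation). Casparian strip genes of the endodermis fell in 6 of 8 cases, also 6 adjusted over the list alone, with CASP4 at −1.11 ± 0.15 (camera adjusted p = 0.0146, adjusted p = 0.273 with an estimated correlation). The other 17 lists did not pass camera in Col. In some of these lists members still moved in both directions. The auxin synthesis genes YUC2 and YUC6 were lower, at −3.21 ± 0.46 and −2.34 ± 0.19, while TAA1 rose by 1.46 ± 0.14. Of 57 SAUR genes 17 rose and 13 fell, or 18 and 13 adjusted over the list alone. Over all 20602 genes tested, 3579 were higher and 3558 lower with NAA, 7137 in all. The count was 11090 with only the Col libraries in the fit 11472 in a fit without the libraries labelled arf2 and 12616 with voom weights.

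The same treatment was then compared in the libraries labelled arf2 and in stop1. GH3.3 rose by 8.99 ± 0.25 in arf2, to 4465 ± 1076 CPM (SD, n = 3), and by 8.08 ± 0.24 in stop1, to 2497 ± 209 CPM. ZFP2, IAA29 and IAA5 rose by 7.08 ± 0.52, 6.85 ± 0.36 and 6.82 ± 0.31 in arf2 and by 8.11 ± 0.58, 6.84 ± 0.37 and 6.90 ± 0.32 in stop1. LBD19, a lateral organ boundaries gene, rose by 6.96 ± 0.34 in arf2 and 6.31 ± 0.36 in stop1. Lower in both were MYB48 at −7.63 ± 0.49 and −4.76 ± 0.37, and CLE2 at −5.27 ± 0.31 and −4.68 ± 0.30, for arf2 and stop1 in that order. In the same order SKOR changed by −5.76 ± 0.28 and −3.92 ± 0.24 and the nitrate transporter gene NPF7.3 by −4.61 ± 0.37 and −4.20 ± 0.37. The heavy metal pump gene HMA2 fell by 5.14 ± 0.26 on the log2 scale in arf2. GAD5 had 1 read in untreated stop1 and 396 with NAA, a ratio of 391 with a 95% counting interval of 69.7 to 15500. STOP1 rose with NAA by 0.83 ± 0.15 in arf2 (edgeR adjusted p = 0.000554), a call that ended only with a 2-fold minimum. Its change was 0.48 ± 0.15 in stop1 (adjusted p = 0.0335, lost in several alternatives). In Col it was 0.32 ± 0.15 (adjusted p = 0.115), called only with library totals, only the compared groups or voom weights. The difference between arf2 and Col did not pass (adjusted p = 0.441).

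Lateral root initiation genes rose in 17 of 21 cases in the libraries labelled arf2 and 16 of 21 in stop1, or 18 and 16 adjusted over the list alone. In that list 1 gene fell in arf2 and 0 in stop1, or 1 and 2 adjusted over the list alone. Aux/IAA genes rose in 23 and 22 of 28 cases, or 23 and 23 adjusted over the list alone, while 2 fell in arf2 and 1 in stop1, or 2 and 2 adjusted over the list alone. Both lists passed camera in both genotypes and held with an estimated correlation, at adjusted p = 0.000318 and 0.000387 in arf2 and 0.000105 for each in stop1. Auxin conjugation and oxidation genes rose in 6 of 8 cases in each, also adjusted over the list alone, with adjusted p = 0.0604 in arf2 and 0.0391 in stop1 with an estimated correlation. Type-A response regulators, known as cytokinin-induced genes, fell in 7 of 9 cases in arf2 and 3 of 9 in stop1, the same adjusted over the list alone, with ARR6 at −2.78 ± 0.54 and −1.94 ± 0.52. Their camera adjusted p was 0.0349 in arf2 and 0.0253 in stop1, with adjusted p = 0.51 and 0.417 with an estimated correlation. Scaled to library totals alone the arf2 camera value was 0.0529. Without arf2_CK replicate 2, arf2_NAA replicate 1 or arf2_NAA replicate 2 it was 0.119, 0.0888 and 0.0524, and without stop1_NAA replicate 2 the stop1 value was 0.0555. Auxin carrier genes rose in 10 of 19 cases in arf2 and 9 of 19 in stop1, or 11 and 10 adjusted over the list alone. Among the carrier genes 1 fell in arf2 and 3 in stop1, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.000157 and 0.00107, adjusted p = 0.283 and 0.337 with an estimated correlation). DNA replication genes rose in 10 and 5 of 14 cases, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.00046 and 0.014, adjusted p = 0.164 and 0.337 with an estimated correlation).

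In arf2, heat shock genes rose in 5 of 10 cases, or 6 adjusted over the list alone, with HSP70 at 2.14 ± 0.42 (camera adjusted p = 0.0349, adjusted p = 0.51 with an estimated correlation). That camera value was 0.152 without arf2_CK replicate 1 and 0.061 without arf2_CK replicate 2. In stop1, photosynthesis genes fell in 8 of 15 cases, or 10 adjusted over the list alone (camera adjusted p = 0.000428, adjusted p = 0.469 with an estimated correlation), and ethylene genes rose in 5 of 10 cases and fell in 1, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.0253, adjusted p = 0.104 with an estimated correlation). Casparian strip genes fell in 4 of 8 cases in stop1, also 4 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.337 with an estimated correlation, and camera adjusted p = 0.0554 without stop1_NAA replicate 3). Iron deficiency genes fell in 5 of 14 cases and rose in 1, F6H1, or 6 and 1 adjusted over the list alone, with BHLH101 at −1.35 ± 0.36 and FRO2 at −1.22 ± 0.26 (camera adjusted p = 0.0294, adjusted p = 0.417 with an estimated correlation). Auxin synthesis genes fell in 4 of 13 cases and rose in 1, TAA1, or 5 and 2 adjusted over the list alone, with CYP79B3 at −2.48 ± 0.20 (camera adjusted p = 0.0341, adjusted p = 0.337 with an estimated correlation, and camera adjusted p = 0.0547 without stop1_NAA replicate 2).

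Of the genes tested, 3743 were higher and 3202 lower with NAA in the libraries labelled arf2, and 2534 were higher and 2160 lower in stop1. Across the 3 genotypes 1870 genes were higher and 1486 lower in all, against 80 and 58 for independent lists of the same sizes. Col shared 4623 called genes of the same direction with arf2 and 3886 with stop1, where 0 and 10 genes were called in opposite directions. With only the compared groups in the fit, the counts were 2615 for arf2 and 7168 for stop1. For stop1 the count was 8384 without the libraries labelled arf2 and 10479 with voom weights. The spread within groups was wider in arf2, with a biological coefficient of variation of 0.336 without NAA and 0.294 with NAA against 0.103 to 0.17 in the other groups. The fit of all libraries used a common spread per gene, so it understated the spread of arf2, and the arf2 counts may be too high. A fit of only the arf2 libraries also had fewer libraries to estimate the spread from.

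**Figure D2:**
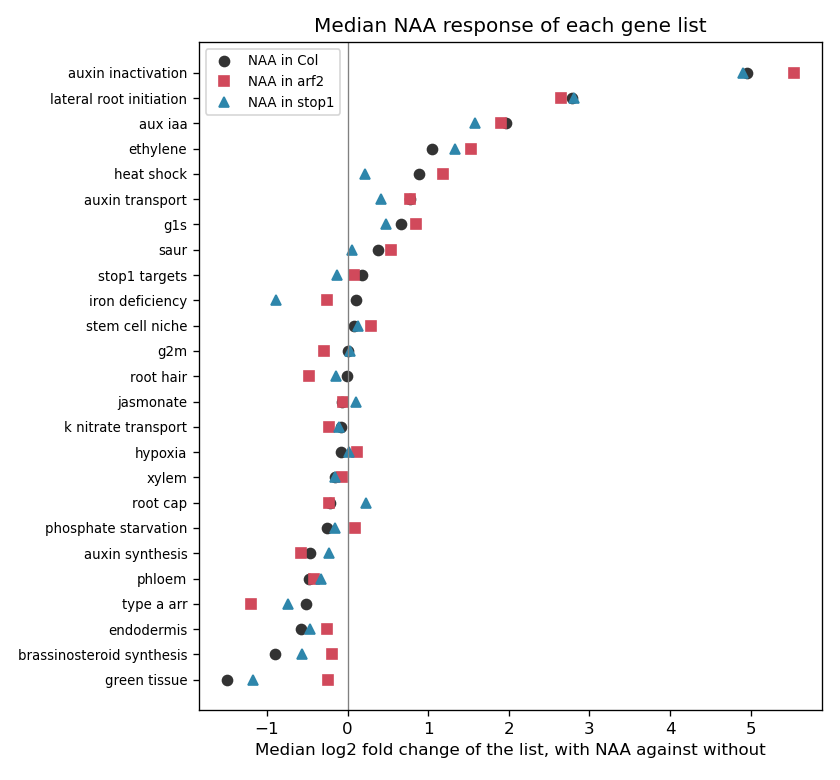
Median log2 fold change of each of the 25 gene lists, with NAA against without, in Col (circles), the libraries labelled arf2 (squares) and stop1 (triangles). Auxin inactivation, lateral root initiation and Aux/IAA genes lay highest in all 3, with medians in Col of 4.96, 2.79 and 1.97, and the median for photosynthesis genes was −1.49 in Col, −0.24 in arf2 and −1.17 in stop1.

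Whether the NAA effect itself differed between genotypes was tested as a difference of differences. GL2, a homeobox regulator of root hair patterning, responded by 0.41 in stop1 and −1.104 in Col, a difference of 1.51 ± 0.20 on the log2 scale. XTH9, a cell wall enzyme gene, responded by 0.70 and −0.97, a difference of 1.66 ± 0.21. DOGT1, a glucosyltransferase gene, had 21.1 ± 6.19 CPM in stop1 with NAA and 0.44 ± 0.23 CPM without (SD, n = 3), against 0.71 ± 0.57 and 0.63 ± 0.25 CPM in Col, a difference of 5.36 ± 0.80. NIC3, a nicotinamidase gene, responded by −0.73 in stop1 and −2.09 in Col, a difference of 1.36 ± 0.22, and lost the call with the replicate block. Over all genes 6 differences were positive and 1 negative, with adjusted p from 0.0109 to 0.0467 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 1254 genes at an unadjusted p under 0.05. DESeq2 called 100 and voom weights 1447. The fit of only the compared groups, which is also the fit without the libraries labelled arf2, called 160, of which 122 were positive and 38 negative. The count was 35 with the length trend removed, 15 with no low-count filter, 18 with a mean of at least 5 CPM and 4 with the replicate block. Of 100 groupings of the samples, the real one included, 9 called at least as many as 7. The other groupings mixed genotypes within a treatment and could carry the genotype effect. They therefore cannot measure chance, which was not excluded. The count was 4 without col_CK replicate 2, 3 without col_CK replicate 3, 15 without col_NAA replicate 1, 2 without col_NAA replicate 2, 3 without col_NAA replicate 3, 0 without stop1_CK replicate 2, 2 without stop1_CK replicate 3, 4 without stop1_NAA replicate 1, 4 without stop1_NAA replicate 2 and 18 without stop1_NAA replicate 3.

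For the libraries labelled arf2 against Col, no gene passed for the difference of the NAA effect in edgeR's quasi-likelihood test, against 2332 genes at an unadjusted p under 0.05 21 called by DESeq2 and 1403 with voom weights. The edgeR test therefore did not show that GH3.3, SKOR and MYB48 responded differently in these libraries. Tests on simulated counts recovered 14% of 2-fold and 76% of 4-fold differences for this comparison. These counts had the same spread per gene in every group. The biological coefficient of variation was 0.336 and 0.294 in the arf2 groups against 0.103 to 0.17 in the others, so recovery here may be lower. Without arf2_CK replicate 2 the count was 1, and without arf2_NAA replicate 1 it was 4.

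The effect of the stop1 genotype was compared without NAA. MRD1 had 2 reads in the 3 stop1 libraries and 3414 in Col, a ratio of 1790 with a 95% counting interval of 496 to 14800. ALMT1, which encodes the malate channel of aluminium resistance, had 3 reads against 471, a ratio of 165 with an interval of 56.0 to 802. STOP2, the closest homolog of STOP1, fell by 8.36 ± 0.55 on the log2 scale, from 28.9 ± 7.05 to 0.08 ± 0.07 CPM (SD, n = 3). The protein kinase gene CIPK23 fell from 138 ± 8.74 to 8.35 ± 0.36 CPM, a log2 change of −4.05 ± 0.16, and PGIP1, a polygalacturonase inhibitor gene, changed by −4.02 ± 0.18. QQS, FRO4, SLAH1, MLO6 and GSTF14 were also lower, at −4.71 ± 0.39, −4.42 ± 0.43, −3.88 ± 0.20, −3.60 ± 0.19 and −3.25 ± 0.39. Higher in stop1 were the vegetative storage protein genes VSP2 and VSP1 at 4.04 ± 0.62 and 3.52 ± 0.60, NDB4 at 3.94 ± 0.32 and the auxin oxidase gene DAO2 at 3.56 ± 0.44. Further increases were CYP71A19 at 3.07 ± 0.37, the triterpene synthase genes MRN1 and THAS1 at 2.88 ± 0.60 and 2.60 ± 0.38, KIN1 at 2.78 ± 0.28 and the sterol desaturase gene CYP710A2 at 2.66 ± 0.42. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ranged from 7.71e-10 for CIPK23 to 0.00581 for MRN1.

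Of 18 genes published as activated by STOP1, 12 fell and 1, the sulphate transporter gene SULTR3;5, rose by 1.19 ± 0.29, or 13 and 1 adjusted over the list alone. The list passed camera at adjusted p = 7.11e-16 with Benjamini-Hochberg adjustment and held with an estimated correlation at adjusted p = 0.00117. Xylem vessel genes rose in 4 of 8 cases, or 6 adjusted over the list alone, with XCP2 at 0.79 ± 0.13 and XCP1 at 0.67 ± 0.20 (camera adjusted p = 0.000727, adjusted p = 0.178 with an estimated correlation). Jasmonate genes rose in 4 of 11 cases, or 5 adjusted over the list alone (camera adjusted p = 0.0202, adjusted p = 0.178 with an estimated correlation). Mitotic genes had a median of 0.22 with 1 of 19 members higher, also 1 adjusted over the list alone (camera adjusted p = 0.0437, adjusted p = 0.471 with an estimated correlation). Their camera adjusted p was 0.0522 without col_CK replicate 1, 0.105 without col_CK replicate 3 and 0.119 without stop1_CK replicate 2. Over all genes 879 were higher and 1576 lower, 2455 in all, against 5847 with only these groups in the fit, 6382 without the libraries labelled arf2 and 8535 with voom weights. The count was 1350 without col_CK replicate 2, 1121 without col_CK replicate 3, 1615, 1062 and 1362 without stop1_CK replicates 1, 2 and 3.

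With NAA, the same contrast gave DOGT1 at 4.87 ± 0.53, DAO2 at 4.03 ± 0.46, CYP710A2 at 3.52 ± 0.46, VSP1 at 3.43 ± 0.60 and CYP71A19 at 3.303 ± 0.414 as the largest increases. MRD1 had 3 reads against 4086, a ratio of 1340 with a 95% counting interval of 460 to 6520. CYP82C4, a gene of the iron deficiency response, had 1 read against 674, a ratio of 665 with an interval of 119 to 26300. STOP2, ALMT1 and FRO4 were lower, at −6.91 ± 0.47, −6.65 ± 0.38 and −4.41 ± 0.43. Of the 18 STOP1-activated genes 14 fell and 1 rose, or 15 and 1 adjusted over the list alone, at camera adjusted p = 1.26e-23 and adjusted p = 0.000166 with an estimated correlation. Xylem genes rose in 3 of 8 cases and jasmonate genes in 4 of 11, or 7 and 5 adjusted over the list alone with 1 jasmonate gene lower (camera adjusted p = 0.000272 and 0.00354, adjusted p = 0.119 for each with an estimated correlation). Root hair genes had 1 of 11 members higher and 1 lower, or 4 and 1 adjusted over the list alone, and mitotic genes 1 of 19 higher, or 0 adjusted over the list alone. Both had a camera adjusted p = 0.0487 and adjusted p = 0.345 with an estimated correlation. Without col_NAA replicate 2, stop1_NAA replicate 1 or stop1_NAA replicate 3 those camera values were 0.0793, 0.0769 and 0.0844 for root hair genes and 0.0692, 0.0572 and 0.0777 for mitotic genes. Without col_NAA replicate 3 the root hair value was 0.0832. Scaled to library totals alone the value for mitotic genes was 0.107. Over all genes 980 were higher and 925 lower, 1905 in all, and 1025 of these were also called without NAA in the same direction, against 5 called in opposite directions. The count was 3375 with only these groups in the fit, 4269 without the libraries labelled arf2 and 6616 with voom weights. It was 1061 without col_NAA replicate 2, 1134 without col_NAA replicate 3 and 1111 without stop1_NAA replicate 1.

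Few genes were called between the libraries labelled arf2 and Col without NAA. HSFB2A fell by 4.66 ± 0.64 on the log2 scale, from 15.6 ± 6.25 to 0.61 ± 0.52 CPM (SD, n = 3), with adjusted p = 0.00553 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. QQS, a regulator of carbon and nitrogen allocation, changed by −4.41 ± 0.38 and the endoglucanase gene GH9B15 by −4.91 ± 0.79. The amino acid transporter family gene UMAMIT17 changed by −1.48 ± 0.26 and MAM1, a gene of methionine-derived glucosinolate synthesis, by −1.47 ± 0.26. TCP3, a growth regulator gene, rose by 1.07 ± 0.19. With only these groups in the fit HSFB2A, GH9B15, UMAMIT17, MAM1 and TCP3 lost the call. So did GH9B15, UMAMIT17 and TCP3 with the replicate block, and HSFB2A and GH9B15 with voom weights. The HSFB2A change itself was −4.67 with only these groups and −5.06 with voom weights. Hypoxia response genes had a median of 0.90, and 0 of 11 members passed over all genes while 6 rose adjusted over the list alone, with LBD41 at 1.41 ± 0.36, PDC1 at 1.32 ± 0.42 and HB1 at 1.22 ± 0.37 (camera adjusted p = 1.51e-06, adjusted p = 0.329 with an estimated correlation). SAUR genes, type-A response regulators and phosphate starvation genes also passed camera, with medians of 0.41, 0.64 and −0.28 and no member called over all genes or adjusted over the list alone. Their camera adjusted p was 0.000265, 0.0237 and 0.0114 (adjusted p = 0.736, 0.736 and 0.541 with an estimated correlation). Without arf2_CK replicate 2 these 3 camera values were 0.0968, 0.425 and 0.0986. That library had a slope of −0.366 over transcript length, so its shorter transcripts read higher. The SAUR median was 0.172 without it and 0.158 with the length trend removed in all libraries, and the median of the regulators was 0.181 without it. Without col_CK replicate 2 the camera values of SAUR genes and response regulators were 0.2 for each, with a SAUR median of 0.162, and without arf2_CK replicate 3 the camera value of the regulators was 0.0753. Transcripts of 17 seed storage and oil body genes summed to 163, 18.18 and 24.1 CPM in these libraries and to 4.14 to 4.80 CPM in untreated Col and stop1. In all 13 genes were higher and 12 lower, against 2745 at an unadjusted p under 0.05, 257 called by DESeq2 and 5 with only these groups in the fit. The count was 61 without arf2_CK replicate 1, 50 without arf2_CK replicate 3, 10 without col_CK replicate 2 and 9 without col_CK replicate 3.

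Changes in the libraries labelled arf2 and in stop1 were compared against the same 3 untreated Col libraries. Both directions together, 17 genes changed the same way, 9 higher and 8 lower, among them QQS, and 4 changed in opposite directions. Independent lists of these sizes would share 0.6 higher and 0.9 lower genes. Unchanged groups and their controls, all simulated from the Col means, shared 0. With no real change to call, a count near 0 was set in advance. It therefore does not show how many of the 17 came through the shared controls. Across genes, which are not independent replicates, the log2 changes had r = 0.226, below the mean of 0.498 ± 0.013 (SD) over 20 simulations of unchanged groups, and a covariance of 0.076 against 0.058 in the simulations, a difference of 0.018. The simulations used the spread per gene over all 18 libraries. The biological coefficient of variation was 0.336 and 0.294 in the arf2 groups but 0.149 in untreated Col. The simulations therefore do not show how much of the covariance came from the shared controls. The simulated comparisons shared their controls too, so the 0.058 already holds such a part. The 3 controls could not be divided into a pair of sets of at least 2. Part of the observed overlap and covariance may therefore come from the shared controls, and how much was not measured. The shared count was 11, 6 and 7 without col_CK replicates 1, 2 and 3, 82 with DESeq2 and 4 with only the compared groups in each fit.

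More genes were called between the libraries labelled arf2 and Col with NAA, 2660 against 25 without NAA. With only the compared groups in the fit the counts were 12 and 5, and in edgeR no gene passed for the difference of the NAA effect. The counts therefore do not show that NAA widened the difference. With NAA, HB33, a homeodomain gene known to be repressed by ARF2, rose by 3.95 ± 0.59, from 0.39 ± 0.15 to 6.14 ± 1.97 CPM (SD, n = 3), with adjusted p = 0.00215 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without NAA it had 0.90 ± 0.65 CPM in Col and 3.06 ± 1.45 CPM in arf2. That change was 1.77 ± 0.54 with adjusted p = 0.228 in the same edgeR test. The difference of its NAA effect was 2.18 ± 0.79 with adjusted p = 0.441 in that test. HSFB2A with NAA changed by −5.44 ± 0.70 on the log2 scale, UMAMIT17 by −2.55 ± 0.31, and the glucosinolate synthesis genes IMS2 and CYP79F2 by −2.389 ± 0.255 and −2.196 ± 0.297. The seed protein genes CRU3, M17, TIP3;1 and OLEO1 rose by 5.39 ± 1.56, 4.66 ± 1.09, 4.42 ± 1.36 and 4.06 ± 1.27, and the 17 seed genes summed to 27.5, 208 and 198 CPM in these libraries against 26.8, 2.33 and 1.84 CPM in Col. STOP1 rose by 0.51 ± 0.15 with adjusted p = 0.0449 in the same edgeR test with Benjamini-Hochberg adjustment. It lost the call with library totals alone (0.245 and adjusted p = 0.229) and with the replicate block (0.513 and adjusted p = 0.0685). The same held with only these groups in the fit (0.479 and adjusted p = 0.149) and with no low-count filter (0.514 and adjusted p = 0.0524). The call also ended without arf2_CK replicate 2 and arf2_NAA replicate 3 together (adjusted p = 0.0878), with a 2-fold minimum, and without arf2_NAA replicate 2 or 3 or any one col_NAA replicate (adjusted p = 0.0933, 0.202, 0.0853, 0.0893 and 0.154).

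Hypoxia response genes rose in 5 of 11 cases in this contrast, or 6 adjusted over the list alone, with PDC1 at 1.35 ± 0.42 and PCO2 at 1.25 ± 0.27 (camera adjusted p = 0.00421, adjusted p = 0.702 with an estimated correlation). Auxin conjugation and oxidation genes rose in 3 of 8 cases, or 5 adjusted over the list alone, with GH3.1 at 1.097 ± 0.250 and GH3.3 at 0.63 ± 0.18 (camera adjusted p = 0.0234, adjusted p = 0.702 with an estimated correlation, and camera adjusted p = 0.0578 without col_NAA replicate 1). SAUR genes rose in 5 of 57 cases, or 3 adjusted over the list alone, and mitotic genes fell in 2 of 19, or 7 adjusted over the list alone (camera adjusted p = 0.0188 for each, adjusted p = 0.704 and 0.702 with an estimated correlation). Their medians were 0.42 and −0.32, against 0.305 and −0.381 with the length trend removed and 0.14 and −0.573 with library totals alone. The slope over transcript length was −0.605 in arf2_NAA replicate 3 and −0.297 in arf2_NAA replicate 2. Of 14 iron deficiency genes 4 were lower, S8H, CYP82C4, FRO2 and IRT1, at −3.27 ± 0.79, −1.99 ± 0.34, −1.89 ± 0.27 and −1.66 ± 0.45. BHLH39 was higher by 0.79 ± 0.20, so 1 rose, with the same counts adjusted over the list alone, in a list with a median of −0.18 that did not pass camera. Of the genes named for this contrast, only HB33 and UMAMIT17 kept the call with only these groups in the fit. CRU3, TIP3;1, OLEO1, GH3.3 and PDC1 also lost it with library totals alone and with the replicate block, PCO2 and BHLH39 with the totals and IRT1 with the block. Over all genes 1822 were higher and 838 lower, 2660 in all and 68.5% higher. Of the 760 that changed at least 2-fold, 419 were higher and 341 lower. There were 963 and 32.6% with library totals alone, a scaling that moved the median of all genes by −0.26. DESeq2 called 5376 genes, 58% higher, but 499 higher and 836 lower at 2-fold or more, a fit of only these groups called 12, the replicate block 800 and voom weights 14125, with 780 higher and 1488 lower at 2-fold or more. The count was 8962, 285 and 164 without arf2_NAA replicates 1, 2 and 3, and 327, 281 and 146 without col_NAA replicates 1, 2 and 3. It was 432 without arf2_CK replicate 2 and arf2_NAA replicate 3, whose read levels fell most with transcript length.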

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

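The lists, the rule that named genes and the tests of the differences below were fixed before the data were examined. The rule took called genes with the largest changes, so the genes themselves were picked from the data, and the 3 genes without a symbol were named after their values were seen. A result stands here because the NAA effect in a mutant label differed from that in Col by a test of the difference itself.

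In stop1, DOGT1 responded to NAA by 5.55 on the log2 scale against 0.19 in Col, a difference of 5.36 ± 0.80 (SE). GL2 changed by 0.41 in stop1 and −1.10 in Col, a difference of 1.51 ± 0.20. XTH9 changed by 0.70 and −0.97, a difference of 1.66 ± 0.21, and the nicotinamidase gene NIC3 by −0.73 and −2.09, a difference of 1.36 ± 0.22. AT4G33420 had a difference of 1.32 ± 0.18, AT5G10580 of 1.27 ± 0.19 and AT5G26670 of −1.41 ± 0.23. Their adjusted p ranged from 0.0109 to 0.0467 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 100 splits of the samples, the real one included, 9 gave at least 7 genes, and the highest other split gave 600. These splits mix genotypes within a treatment, so they can carry the stop1 effect itself, which called 2455 genes without NAA and 1905 with NAA. They therefore cannot measure chance for this difference, and chance was not excluded. The cause of the difference was not tested. The count was 0 without stop1_CK replicate 2, and DOGT1 had an adjusted p between 0.0644 and 0.128 in 8 of these fits.

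In stop1 the iron deficiency list had a median difference of −0.45, the heat shock list of −0.67 and the DNA replication list of −0.30, with camera adjusted p = 0.000785, 0.027 and 0.019. Adjusted p with an estimated correlation was 0.409, 0.59 and 0.409. No member was called over all genes, and adjusted over the list alone 1 iron deficiency gene and 1 DNA replication gene had a negative difference of the NAA effect, which need not be a fall. The iron deficiency median was −0.214 without col_CK replicate 1, −0.726 without col_CK replicate 3, −0.192 without stop1_CK replicate 1 and −0.777 without stop1_NAA replicate 2. The heat shock median was −0.328 without col_CK replicate 1 and −0.391 without col_NAA replicate 2. The heat shock call ended with library totals alone (0.0619) and without col_CK replicate 1 (0.13), col_NAA replicate 2 (0.16), stop1_CK replicate 3 (0.124), stop1_NAA replicate 1 (0.052) or stop1_NAA replicate 3 (0.0953), and the DNA replication call without col_NAA replicate 3 (0.104), stop1_CK replicate 2 (0.0584) or stop1_NAA replicate 1 (0.052).

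In the libraries labelled arf2 the photosynthesis list had a median difference of 1.28, the auxin carrier list of 0.38 and the iron deficiency list of −0.44, with camera adjusted p = 0.000658, 0.00329 and 0.0448 and adjusted p = 0.625 for each with an estimated correlation. No member was called over all genes or adjusted over the list alone. The photosynthesis list summed to 293, 599 and 665 CPM in arf2_NAA replicates 1, 2 and 3 and to 274 to 338 CPM in Col with NAA. Replicates 2 and 3 also had more seed transcripts, 207.9 and 197.8 CPM against 27.53 in replicate 1, and steeper slopes over transcript length, −0.297 and −0.605 against −0.077. The photosynthesis median was 0.836 without arf2_NAA replicate 2. The auxin carrier median was 0.192 with library totals alone and 0.641 without arf2_CK replicate 1, and the iron deficiency median was −0.188 without arf2_CK replicate 2. Without arf2_CK replicate 2 and arf2_NAA replicate 3 together these medians were 0.072 and −0.263. The auxin carrier call ended without arf2_CK replicate 2 (0.101), and the iron deficiency call with library totals alone (0.0533) and without that library (0.112), arf2_NAA replicate 1 (0.125), arf2_NAA replicate 2 (0.108), col_CK replicate 1 (0.17), col_NAA replicate 1 (0.0704) or col_NAA replicate 3 (0.0533). All 100 splits gave at least the 0 genes of the real one, which a count of 0 makes certain, so this comparison says nothing about chance. Of these splits 5 called any gene, the highest 5294.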

How the results depend on the processing

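The 4 alternatives named last were chosen after the data were seen: length trend removed, voom weights, no arf2 libraries and 2 libraries left out together. Over all alternatives, named genes kept their side of the threshold in 7471 values, lost the call in 955 and gained it in 11. Apart from ARF2 and STOP1, only genes called in the main fit were entered. No other gene could gain a call, so the number of gains does not measure stability. Called lists kept the call in 430 and lost it in 96. Direction was compared only where the main fit or the alternative made a call, and there none reversed. Causes were not tested unless stated.

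Counts of called genes that moved by over 1.5 times were as follows. With only the compared groups in the fit, NAA gave 11090 genes in Col, 2615 in arf2 and 7168 in stop1, arf2 against Col gave 5 without and 12 with NAA, stop1 against Col 5847 and 3375, the stop1 difference 160, and the arf2 and stop1 overlap 4. The wider spread of the arf2 libraries then no longer entered the other comparisons, and the narrower spread of the groups left out no longer entered those of arf2. Without the arf2 libraries the counts were 11472 and 8384 for NAA in Col and stop1, 6382 and 4269 for stop1 without and with NAA, and 160 for its difference. DESeq2 gave 257 and 5376 for arf2 without and with NAA, 21 and 100 for the arf2 and stop1 differences, and an overlap of 82. Voom weights gave 12616 and 10479 for NAA in Col and stop1, 8535 and 6616 for stop1, 14125 for arf2 with NAA, 1403 and 1447 for the differences and 5173 shared by all NAA responses; they gave arf2_NAA replicate 2 a weight of 15.1 and the other libraries 0.1 to 3.02. A 2-fold minimum, stricter by construction, gave 3232, 3224 and 2089 for NAA in Col, arf2 and stop1, 889 and 957 for stop1, 760 for arf2 with NAA, an overlap of 10 and 1461 shared by all. Library totals alone gave 963 for arf2 with NAA. Length trend removed gave 39 for arf2 without NAA and 35 for the stop1 difference. The stop1 difference was 15 with no filter and 18 with a 5 CPM minimum, where the overlap was 11. Without arf2_CK 2 and arf2_NAA 3, arf2 with NAA gave 432. With an estimated correlation 9 of 49 list calls held, and with fry 38.

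With all libraries kept, the share of higher calls moved by over 10 points for arf2 with NAA (68.5%, against 32.6% with totals, 58% with DESeq2, 53.1% with voom and 419 of 760 genes with a 2-fold minimum), stop1 without NAA (35.8%, against 47.4% with only these groups and 46.6% with voom) and the stop1 difference (85.7%, against 55% with DESeq2, 100% with the block, 62.9% with the length trend removed and 60.1% with voom). Leaving out 1 library moved it to 52.3 and 79.6% for arf2 with NAA (arf2_NAA replicates 1 and 2), to 40% from 52% for arf2 without NAA (col_CK replicate 2), and to 61.7 and 65.6% from 51.4% for stop1 with NAA (stop1_NAA replicates 1 and 3). At 2-fold or more, DESeq2 and voom called more genes lower than higher for arf2 with NAA (836 against 499 and 1488 against 780). For the stop1 difference the share was 75% without stop1_NAA replicate 2 and 100% in 7 of these fits. Totals moved the median of all genes by −0.26 for arf2 with NAA and −0.179 for its difference.

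Leaving out 1 library at a time gave 5201 to 6434 genes for NAA in Col, 5542 to 7552 in arf2 and 3355 to 3996 in stop1, 9 to 61 and 146 to 8962 for arf2 without and with NAA, 1062 to 1647 and 1061 to 1422 for stop1, 0 to 4 and 0 to 18 for the arf2 and stop1 differences, 6 to 20 for the overlap, 2671 to 3455 for all NAA responses and 43 to 56 list calls. Other list medians that moved by over 1.5 times were those of jasmonate genes in stop1 without NAA (0.835 from 0.389, col_CK replicate 2), heat shock genes for NAA in arf2 (0.76 from 1.178, arf2_CK replicate 1), type-A regulators for NAA in arf2 (−0.634 from −1.201, arf2_CK 2 and arf2_NAA 3), auxin conjugation genes in arf2 with NAA (0.316 from 0.6, totals), auxin carriers for NAA in stop1 (0.649 from 0.414, length trend removed) and auxin synthesis genes for NAA in stop1 (−0.346 and −0.42 without stop1_CK replicates 1 and 3 and −0.483 without stop1_NAA replicate 2, from −0.227).

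Samples share only a replicate number: 14 of 45 same-number pairs had a correlation of deviations over 0.1, from −0.615 to 0.482, and 7 of 18 libraries correlated best with their own number. The replicate block gave 800 genes for arf2 with NAA, 4 for the stop1 difference and an overlap of 10, and moved no other count by over 1.5 times. Depth was alike in all libraries, so it limits only genes with few reads.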

Other observations

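The 3 lists in the next paragraph and all tests of the patterns after it were chosen after values were seen, except the length trend within classes of expression and the splits of the samples. The lists were adjusted over their own family of 3 and were picked partly from called genes, so their p-values are not independent evidence.

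Genes of methionine-derived glucosinolate synthesis, a chemical defence of the cabbage family, fell with NAA in 9 of 12 cases in Col, 9 in the libraries labelled arf2 and 11 in stop1, with medians of −1.88, −2.21 and −1.53. Between genotypes they moved apart: in stop1 10 of 12 rose without NAA and 9 with NAA, with medians of 1.27 and 1.35, while in the libraries labelled arf2 1 fell without NAA and 7 with NAA, with medians of −0.92 and −1.61. In camera with an estimated correlation the adjusted p was 0.0223 and 0.0161 in stop1 and 0.0223 and 0.0689 in arf2, without and with NAA, and 0.101, 0.0886 and 0.0316 for NAA in Col, arf2 and stop1. Genes of the root triterpene clusters, which include MRN1 and THAS1, rose in stop1 in 6 of 7 cases without NAA and 6 with NAA, with medians of 1.68 and 2.39 (adjusted p = 0.054 and 0.0161 with an estimated correlation). They fell with NAA in 6 of 7 cases in Col, 2 in arf2 and 3 in stop1 (adjusted p = 0.265, 0.392 and 0.402 with an estimated correlation). The seed list, with 12 of its 17 members tested, had medians of 4.84 and 3.62 in arf2 against Col without and with NAA, with 0 and 7 members called (adjusted p = 0.0526 and 0.149 with an estimated correlation).

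Read levels depended on transcript length differently in single libraries. The slope of log2 CPM against the Col mean, per doubling of length, ran from −0.171 to 0.17 in the 12 Col and stop1 libraries, and was −0.605 in arf2_NAA replicate 3, −0.366 in arf2_CK replicate 2, −0.297 in arf2_NAA replicate 2 and −0.192 in arf2_CK replicate 1. The other 2 libraries labelled arf2 lay inside the range of Col and stop1, which argues against the genotype as the whole cause. All 4 libraries outside it had a slope of the same sign in genes of low, middle and high expression, as RNA fragmentation or fragment size selection in single libraries may give. So did every library inside the range, for example col_CK replicate 1 at −0.043, −0.036 and −0.003. The sign therefore does not set the 4 libraries apart and decides nothing about these causes. Whether the 4 libraries were prepared apart was not tested. With the trend removed, 3444 genes were called in arf2 against Col with NAA, where 2660 were called before. Counts also rose without arf2 in the comparison, from 7137 to 8217 for NAA in Col and from 2455 to 3118 for stop1 without NAA. The rise therefore does not show how many of the 2660 calls came from the trend.

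CRA1, a seed storage protein gene, had 32 to 1823 reads in the 6 libraries labelled arf2 and 0 to 4 in most others, but 287 in col_NAA replicate 1 and 149 in stop1_NAA replicate 2, more than in arf2_CK replicate 2. This argues against the arf2 genotype as the whole cause. Seed or embryo material in the harvest may be a source, for which most of the 17 seed genes should be higher in all 6 arf2 libraries than in every untreated Col and stop1 library. This was so for 8 of 17, or 47.1%, just under the bound of 50% of members set for the test, but the exact binomial interval of 23 to 72.2%, added once that value was known, includes 50%, and 5 of the members were too low to pass the filter. The interval treats the 17 genes as independent, though all were read in the same 6 libraries, so it may be too narrow. The test therefore does not decide, and seed material cannot be told apart from expression of these genes in some root tips.

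HSFB2A was nearly absent in the libraries labelled arf2. Its highest count there was 23, against at least 200 in each other library. This restates the pattern on the gene that showed it, so it does not test the labels, and a mislabelled sample was not excluded by it. The other 16 tested genes within 50 kb had median log2 changes of −0.216 without NAA and −0.275 with NAA, which argues against loss of the whole neighbourhood. A change at this locus in the arf2 line, for example beside ARF2, may be a cause and was not tested, and reads from an antisense transcript could not be told apart without strand. Within the compared groups alone the adjusted p was 0.217 without NAA and 0.0527 with NAA, at log2 −4.67 and −5.47, and with voom weights it was 0.551 without NAA.

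With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each of the 7 direct comparisons 1 split, the real one, gave as many genes. The real counts were 7137, 6945 and 4694 for NAA in Col, arf2 and stop1, 25 and 2660 for arf2 against Col without and with NAA, and 2455 and 1905 for stop1. The highest other split gave 3683 for NAA in arf2 and 0 in the other 6. For NAA in arf2 other splits also gave 292, 438 and 1792. Every other split mixes the real groups, so a real difference widens the spread within its groups and lowers its count. A count of 0 there therefore says nothing about chance, which was not excluded.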
